A study of Mus musculus with 24 samples.

How the data were processed

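The data were small RNA libraries of mouse CD4+ T cells and of the extracellular vesicles (EVs) that these cells released into the culture medium. Per the submitters' processing notes, reads were aligned with Bowtie, and the genome builds named were GRCm38 and mm10. The aligner's version and settings, adapter trimming, the treatment of reads with several alignments, the annotation release and the counting tool were not given in the sources used here. Per the file headers, each library's file held 1 read count per annotated feature, and the values were whole numbers. The deposited count files listed 4441 lines each, of which 33 repeated another line in full and were dropped, which left 4408 features. The smallest count in any deposited file was 4, so features with fewer reads in any library had been left out by the authors, and their number was not given in the sources used here.

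The features were sorted by name into 254 miRNAs, 780 nuclear tRNA features, 10 mitochondrial tRNAs, 152 snoRNAs, 57 snRNAs, 70 rRNA features, 3 Y RNAs and vault RNAs, 14 other small RNAs, 26 predicted miRNA loci, 2692 protein-coding genes and 350 long non-coding genes. Of the 3612 names outside the tRNAs, 3515 were found in GENCODE M21, which gave the coordinates (GRCm38, counted from 1). The miRNAs were named by precursor, without arms, so a miRNA of a list was matched by its precursor. Some matched several: 9 let-7 names gave 12 features, 4 miR-181 names 6 and 5 miR-232724 names 6. Many of the 70 rRNA features were n-R5s genes, annotated copies of 5S rRNA. Reads may be shared between such precursors or copies. They were not summed in any fit, so counts of members can hold 1 RNA more than once. The tRNA features covered 47 anticodons and were named by locus and by fragment kind, with several loci per anticodon. The names of the kinds are the authors' own: 5FR and 3FR mark fragments of the 5' and 3' ends, numbered 1 and 2 or marked S, and 5_half_up, 3_half_up and 3_half_down mark half-length fragments.

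Reads that fell in a miRNA or snoRNA were also counted for the gene around it in the deposited counts. Of the 2943 protein-coding and long non-coding genes, 204 held a listed small RNA, and these took from 25.5% to 86.1% of a library's counts in long genes. A long gene's count in the deposited files therefore measured small fragments mapped inside it and is not an mRNA level. For 12 pairs of features on opposite strands the counts were equal in every library, among them Mir451a and Mir451b, so the strand had not been separated by the authors for these. Another 5 names (Dancr, Flt3l, Pcdha11, Pde2a and Pik3c2g) stood on several lines whose values combined 2 separately made count tables of the authors, 1 of the 12 resting and stimulated libraries and 1 of the 12 DMSO and GW4869 libraries.

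Counts as deposited by the authors were analysed with edgeR 4.0.16 in R 4.3.3. Features were filtered with filterByExpr (minimum count 10 by group), which removed 0 of the 4408 deposited features. Library sizes were scaled with TMM factors. One quasi-likelihood model without intercept was fitted to the 8 groups and 24 libraries (glmQLFit, glmQLFTest), and a call needed a Benjamini-Hochberg adjusted p under 0.05 over the 4408 features. The contrasts were EVs against cells in resting and in stimulated cultures, stimulated against resting in cells and in EVs, GW4869 against DMSO in EVs and in cells, DMSO against stimulated in cells and in EVs, and 2 difference contrasts of the EV to cell ratio. Folds are log2 values with standard errors (SE) from the same model. Levels are means with standard deviations (SD) of CPM (counts per 1e6) with TMM scaling, computed from the deposited counts, and log CPM values used a prior count of 2.

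The share of each library's deposited counts in 44 sets of features was compared between EVs and cells by a two-sided exact permutation test over the 160000 arrangements of the labels within the 4 conditions, with Benjamini-Hochberg adjustment over the 44 sets. Within 1 condition, 3 libraries against 3 cannot give an exact p below 0.1.

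Lists of features were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between members, adjusted over the 49 lists of a comparison with at least 3 members, and again with an estimated correlation and with fry. The lists were the classes named above, the tRNA fragment kinds, the tRNAs by amino acid, activation-induced miRNAs, miRNAs of naive and resting T cells, the let-7 family, the miR-17~92 and paralogous clusters, the miR-29, miR-30, miR-15/16 and miR-181 families, the miR-232724 clusters, and miRNA markers of other cell types (erythroid, myeloid, platelet and endothelial, liver, epithelial, muscle and stromal). Members were counted as higher or lower by the adjustment over all features and, beside it, by that over the list alone; where 1 number is given for a list, both adjustments gave it.

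The features named for a comparison of 2 groups were the 8 highest and the 8 lowest log2 folds among features with an adjusted p under 0.05, a mean of at least 100 CPM in 1 of the 2 groups and no overlap of the groups' CPM, with at most 1 feature per anticodon and fragment kind. With 3 libraries against 3, chance alone gives no overlap for 10% of features. The 2 difference contrasts used the same rule without the overlap condition. Members of the lists and the 5 most abundant features of each group were named as well. Contrasts, tests, lists, the naming rule and the alternatives were chosen before the data were examined, except the alternatives with tRNA copies summed and host genes left out, those by class without single DMSO or GW4869 EV libraries, and the groupings stated as chosen after their values were seen.

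Alternatives were RLE size factors (median of ratios), library totals without scaling factors, no filter, a stricter filter (at least 10 CPM in at least 3 libraries, which kept 4324 features), the Wald test of DESeq2 1.42.0, a fit of only the groups compared, replicate number as a block, and each library left out in turn. For the shares they were the features past the filter, the log2 ratio of tRNA-derived to miRNA counts in the deposited files, each replicate number left out and permutation within 4096 arrangements of pairs. In simulated counts with 200 changed features of 4408, modelled on the deposited counts, the resting EV comparison recovered 35% of 2-fold and 89% of 4-fold changes with 5 false calls (3.9% of calls), and the comparison of GW4869 with DMSO EVs recovered 36% and 98% with 10 false calls (6.9%). The share test recovered 99% of shifts by 2 SD and called 6% of sets without a shift, in 200 simulated sets. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.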

Results

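Small RNA libraries were sequenced from mouse CD4+ T cells and from the EVs in their culture medium. The T cells came from spleen and lymph nodes of C57BL/6 mice, and RNA was extracted with Trizol. The 24 libraries fell into 8 groups of 3: cells and EVs from resting cultures, from stimulated cultures, and from cultures stimulated with DMSO or with GW4869. Stimulated cells had been cultured for 3 days on plate-bound anti-CD3 (2 µg/ml) and anti-CD28 (5 µg/ml). Resting cells had been stimulated for 2 days, expanded for 1 day and then rested for 2 days in medium with IL2. Stimulated and resting cultures thus also differed in culture time and earlier treatment, and no contrast separates these from the stimulation itself. GW4869 inhibits neutral sphingomyelinase, an enzyme that takes part in the budding of some vesicles, and DMSO was its vehicle. DMSO and GW4869 cultures were also stimulated for 3 days, and no antibody dose was given for them in the labels. The labels do not say whether the 3 libraries of a group came from separate animals or cultures, so the p-values measure the spread between libraries only.

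The total count per library ranged from 1290918 in GW4869 EVs replicate 1 to 3231626 in resting EVs replicate 3. By group, totals were 1962923 to 2268358 in resting cells, 1988062 to 3231626 in resting EVs, 2254908 to 2742635 in stimulated cells and 2202869 to 2731956 in stimulated EVs. They were 1551155 to 2007709 in DMSO cells, 2068951 to 2579407 in DMSO EVs, 1806960 to 2300284 in GW4869 cells and 1290918 to 1663560 in GW4869 EVs. The 10 most abundant features of a library took 31.51% (GW4869 EVs replicate 3) to 62.76% (resting cells replicate 1) of its counts. Mir142 (chromosome 11, 87756864 to 87756927, plus strand), a miRNA of blood cells, led the resting groups, with 230200 ± 18700 CPM in resting cells and 174600 ± 39800 CPM in resting EVs (SD, n = 3). The same reads were counted for Mir142b and Mir142hg. Mir142 stood at 77040 ± 12500 CPM in stimulated cells, 47140 ± 1810 CPM in stimulated EVs and 23370 ± 5900 CPM in GW4869 EVs. The ribosomal feature Rn18s-rs5 was the most abundant in DMSO EVs (49890 ± 9590 CPM) and in GW4869 EVs (35640 ± 4340 CPM).

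Which classes of RNA the vesicles carry, relative to the cells, was asked of all 4 conditions together. The miRNAs, which guide Argonaute proteins to mRNAs, took a smaller share of EV than of cell counts, by a mean of -9.26 percentage points, and were lower in EVs in 4 of 4 conditions. In resting cultures they made up 51.5 ± 1.33% of EV counts and 54.0 ± 0.465% of cell counts, and in GW4869 cultures 22.0 ± 3.71% and 37.1 ± 2.93% (SD, n = 3). These are shares of counts and not of reads. The reads of Mir142 were counted again for Mir142b, also a miRNA, and for Mir142hg, and no miRNA share was computed without such copies. The snoRNAs, which guide the modification of rRNA in the nucleolus, were lower in EVs by a mean of -1.57 points, with 0.49 ± 0.0329% of stimulated EV counts against 2.35 ± 0.128% of stimulated cell counts. The rRNA features and the Y RNAs and vault RNA, which are parts of ribonucleoproteins, had higher shares in EVs in 4 of 4 conditions, by 2.22 and 0.356 points. Nuclear tRNA features together did not differ in the mean over conditions (0.103 points, p = 0.539, adjusted p = 0.552, exact permutation test), since the conditions went in opposite directions. They took 2.78% of EV against 3.15% of cell counts in resting and 3.49 against 2.49% in stimulated cultures, without overlap of libraries in either. In DMSO cultures the shares were 3.4 against 3.21%, and in GW4869 cultures 3.04 against 3.46%. Some fragment kinds did differ in the mean over conditions. The 5FR_1 fragments of the 5' end had higher shares in EVs in 4 of 4 conditions (0.859 points), with 1.58% of stimulated EV counts against 0.352% of stimulated cell counts. The 3FR_2 fragments of the 3' end had lower shares in 4 of 4 conditions (-0.73 points). Long genes without a listed small RNA, a set outside those tested, took larger shares of EV than of cell counts: 8.03 against 5.83% in resting, 27.3 against 19.3% in stimulated, 36.3 against 13.0% in DMSO and 43.6 against 17.5% in GW4869 cultures. A share that grows lowers the others.

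Of the 44 sets in the exact permutation test, 35 passed an adjusted p of 0.05. The miRNA, snoRNA, rRNA, Y RNA and vault RNA, 5FR_1 and 3FR_2 shares had p = 1.25e-05 in the permutation test, the smallest they can give, and an adjusted p of 2.89e-05. Mitochondrial tRNAs fell by -0.191 points over all conditions (adjusted p = 0.000407), although their share was higher in EVs than in cells in resting cultures, 0.0514 ± 0.00246% against 0.0349 ± 0.00183%. The snRNA share was higher in EVs by 0.223 points (adjusted p = 0.00213), and by 0.178 points without replicate 2 (adjusted p = 0.0621). The log2 ratio of tRNA-derived to miRNA counts, which has no denominator in common with other classes, was higher in EVs by 0.472 (p = 0.00035, exact permutation test), with -0.108 in resting and 0.68 in stimulated cultures.

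**Figure D1:**
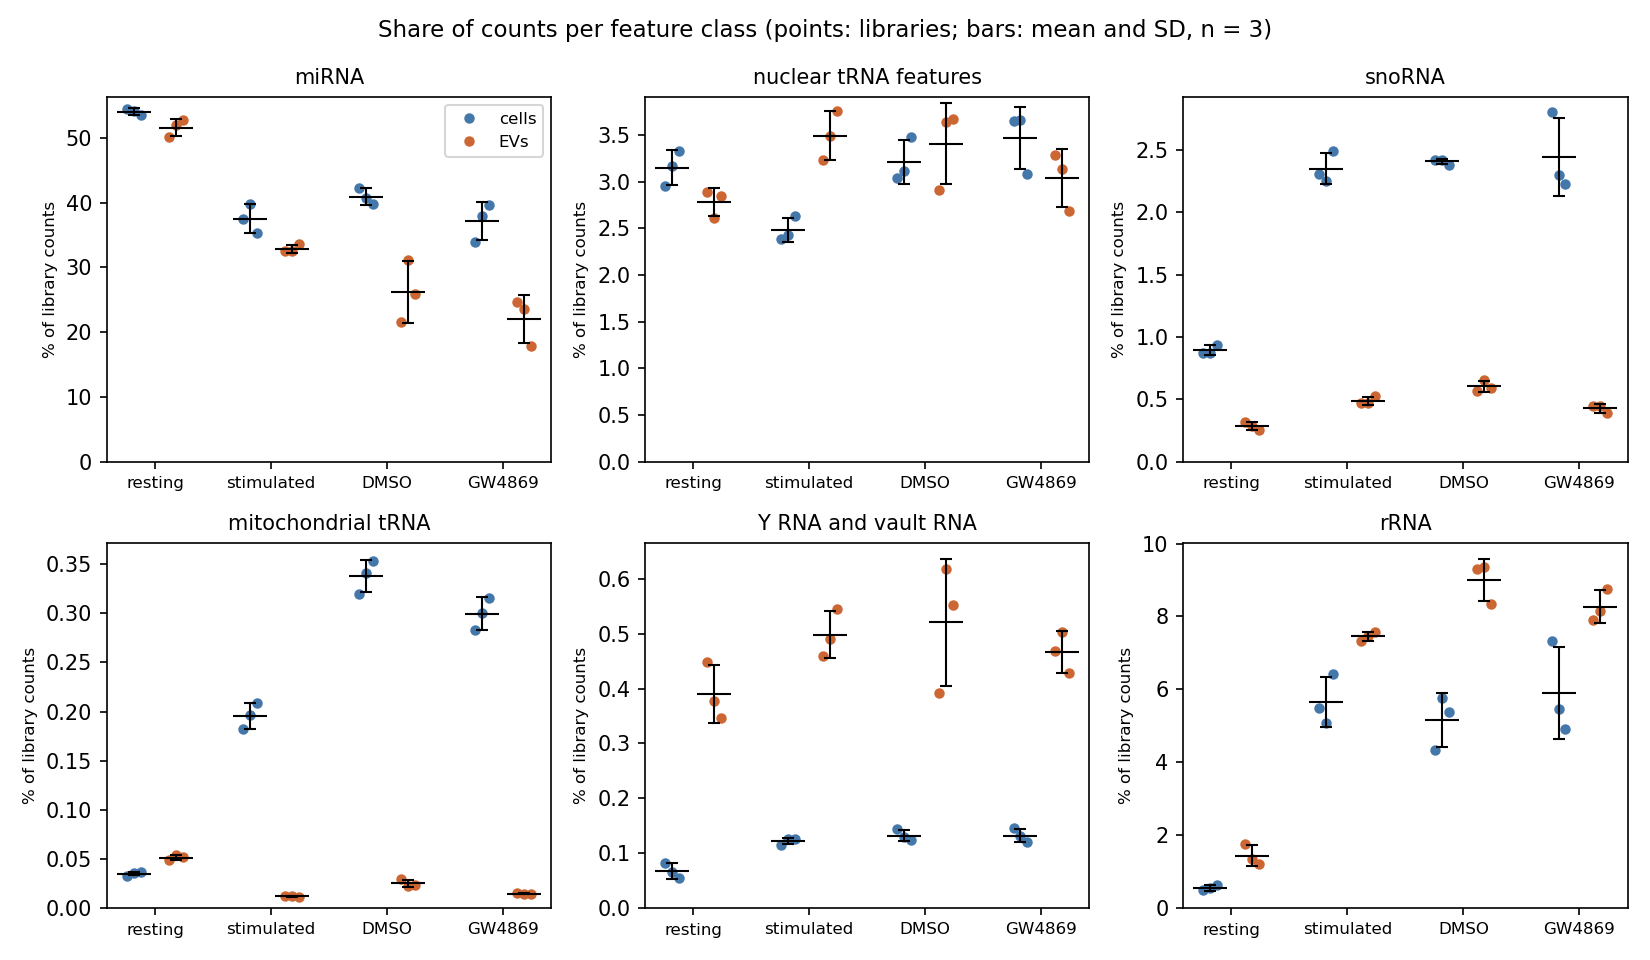
Share of each library's counts (vertical axes, %) in 6 classes of RNA for the 8 groups, with points for libraries and bars for the mean and SD of 3. The snoRNA share of every EV group lies below that of its cells, between 0.286% and 0.605% against 0.892% to 2.45%, and mitochondrial tRNAs are lower in EVs in 3 of the 4 conditions.

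The comparison of EVs with cells in resting cultures asked which RNAs were released or retained by cells at rest after activation. The largest rise in EVs was that of Camk2b (chromosome 11, 5969644 to 6066362, minus strand), the gene of a calmodulin-dependent kinase subunit, by a log2 fold of 6.22 ± 0.25 (SE), from 25.59 ± 4.76 CPM in cells to 1915 ± 86.6 CPM in EVs (n = 3, adjusted p = 1.29e-15). Rny1 (chromosome 6, 47788069 to 47788180, minus strand), a Y RNA bound by the Ro protein, rose by 3.40 ± 0.22, from 407 ± 50.2 to 4287 ± 477 CPM (adjusted p = 8.94e-12), and Rny3 rose by 2.56 ± 0.22, while Vaultrc5 had 0.54 ± 0.31 (adjusted p = 0.2). Of the 152 snoRNAs, 0 were higher and 130 lower in EVs (132 adjusted over the list alone), with a median of -1.72. Snord43, listed in the annotation as a miRNA locus (chromosome 15, 80082847 to 80082954, minus strand), fell by -3.79 ± 0.24, from 412.1 ± 22.8 to 29.88 ± 6.49 CPM. The 254 miRNAs split into 16 higher and 17 lower (9 and 10 adjusted over the list alone), with a median of -0.09 that was 0.05 with library totals.

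The tRNA fragments in resting EVs sorted by kind and by amino acid. The 3FR_2 fragments had 47 of 58 features higher and 8 lower in EVs, with a median of 2.90. With loci summed by anticodon, 11 of 22 were higher and 6 lower (median 0.97), and summed tRNA-Asp-GTC 3FR_2 rose by 3.84 ± 0.28 (adjusted p = 5.95e-11). Summed tRNA-Ala-TGC 3FR_2, far more abundant, fell by -1.29 ± 0.37, from 12220 ± 1610 to 4990 ± 1830 CPM (adjusted p = 0.0083), and summed tRNA-Cys-GCA 3FR_2 fell by -1.18 ± 0.24. The 5FR_1 fragments had 97 of 172 features higher and 9 lower (102 and 11 adjusted over the list alone; median 0.95), whereas the 5FR_2 fragments had 2 of 109 higher and 86 lower (3 and 87 adjusted over the list alone; median -1.86), among them summed tRNA-Asp-GTC 5FR_2 at -3.42 ± 0.24 (adjusted p = 3.41e-11). Of the 38 proline tRNA features 37 were lower, and all 12 threonine features were lower, with medians of -2.60 and -2.28. The serine features went the other way, with 28 of 30 higher (median 1.74).

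Among the 16 features named by rule, the others higher in resting EVs were Rbbp8, Srsf1, Gm24372, Rpl8, Tbce and 1 locus of tRNA-Ala-TGC 3FR_2, whose summed loci fell (4.03 to 4.70). The others lower were Fbxo45, Gm24452, 1 locus of tRNA-Pro-TGG 3FR_1, Tshr, Thoc2 and Gm22680 (-3.62 to -3.35). Rbbp8 acts in the repair of DNA breaks, Srsf1 is a splicing factor, Rpl8 is a protein of the large ribosomal subunit, and Thoc2 belongs to a complex of mRNA export. In each named feature of a comparison between 2 groups, the 3 libraries of 1 group lay above all 3 of the other. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1513 features passed, 834 higher and 679 lower in EVs. With the loci of a tRNA summed and host genes left out, an alternative chosen after seeing the data, 994 features passed. The list tests passed in camera with adjusted p of 2.53e-37 for the snoRNAs, 1.34e-23 for 3FR_2, 5.17e-10 for 5FR_1, 7.12e-31 for 5FR_2, 1.19e-09 for serine, 8.55e-37 for proline and 6.1e-08 for threonine. Proline and threonine kept their calls with an estimated correlation (adjusted p = 0.0129 and 0.0114), and the rest did not: adjusted p = 0.0647 for the snoRNAs, 0.054 for 3FR_2, 0.577 for 5FR_1, 0.0862 for 5FR_2 and 0.128 for serine with an estimated correlation.

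**Figure D2:**
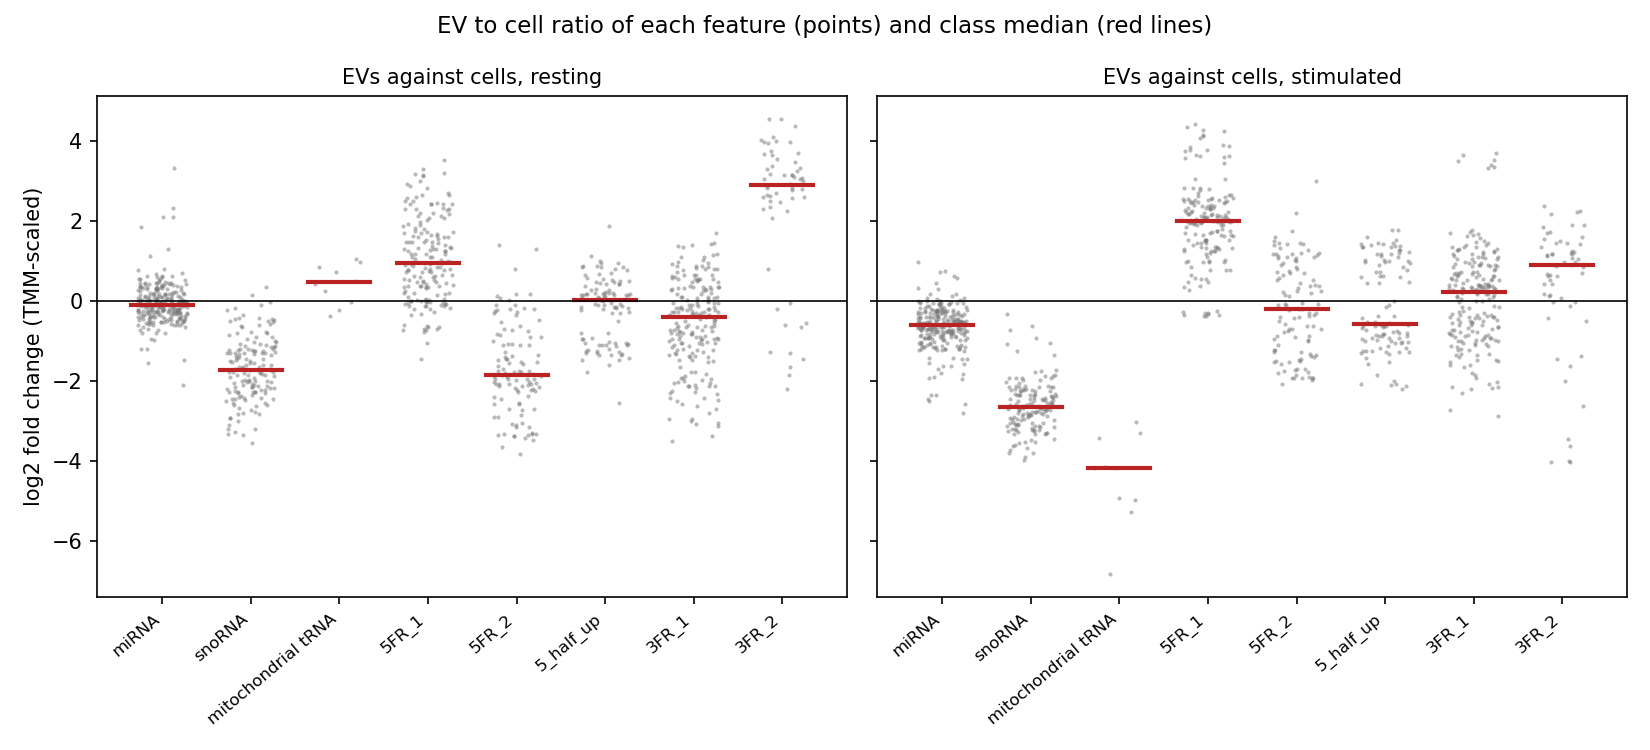
Log2 fold of EVs over cells (vertical axis) for single features of 8 classes and fragment kinds in resting and in stimulated cultures, with TMM scaling and class medians in red. The mitochondrial tRNAs have a median of 0.47 in resting and -4.18 in stimulated cultures, the snoRNAs lie below 0 in both, and the miRNA median of -0.09 in resting cultures becomes 0.05 with library totals.

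The same comparison in stimulated cultures asked which RNAs were released during activation. All 10 mitochondrial tRNAs were lower in EVs, with a median of -4.18, led by mt-Ti (chromosome M, 3706 to 3774, plus strand), the isoleucine tRNA of mitochondria, at -6.84 ± 0.30, from 547.2 ± 147 CPM in cells to 4.763 ± 1.18 CPM in EVs (adjusted p = 2.68e-15, n = 3). Of the snoRNAs 0 were higher and 149 lower (150 adjusted over the list alone), with a median of -2.65. The miRNAs had 4 higher and 123 lower of 254 (4 and 122 adjusted over the list alone), with a median of -0.59 that was -0.15 with library totals, where 17 were higher and 52 lower. The 5FR_1 tRNA fragments had 151 of 172 features higher and 0 lower (153 and 0 adjusted over the list alone), with a median of 2.02, led by 1 locus of tRNA-Gly-TCC 5FR_1 at 4.44 ± 0.29 (adjusted p = 2.4e-12). Rny1 rose again, by 2.85 ± 0.21, from 421.8 to 3036 ± 524 CPM (adjusted p = 2.62e-11).

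Of 12 miRNAs known to rise when T cells are activated, 10 were lower in stimulated EVs than in their cells and 0 were higher (median -1.01). Mir210 (chromosome 7, 141221384 to 141221493, minus strand), a miRNA induced by hypoxia, was lower by -2.34 ± 0.24, Mir182 by -1.61 ± 0.24, Mir132 by -1.11 ± 0.21 and Mir155 (chromosome 16, 84714140 to 84714204, plus strand), which cells need for normal immune responses, by -0.60 ± 0.17 (adjusted p = 0.00475). Library totals moved the median fold of all features up by 0.44 in this comparison, so the smaller falls depend on the scaling. The fall of Mir155 lay near the median of all miRNAs and does not set it apart from its class. The 4 miRNAs higher in stimulated EVs were Mir150, by 0.99 ± 0.22 (adjusted p = 0.000471), Mir181a-1, Mir181a-2 and, chosen after its values were seen, Mir6236. Fragments within Fam49a (6.77 ± 0.46, from 5.536 ± 2.31 to 621.1 ± 117 CPM) and within Tcf7 (4.55 ± 0.39), the gene of a transcription factor of naive T cells, rose in EVs, as did those in Fam19a1, Foxo3, Obox1, Obox3 and Mcf2l (4.42 to 4.97). Fragments in Mapk15, Gm14321, Fbxo45 and Scarb2 fell, as did mt-Ts2, mt-Ta and mt-Tl1 (-5.35 to -4.89). The 70 rRNA features had 61 lower and 2 higher (62 and 2 adjusted over the list alone), with a median of -0.87, although their summed share of counts was higher in EVs. Many of these features are n-R5s copies, so the numbers do not count separate RNAs. Summed tRNA-Ala-TGC 3FR_2 fell by -3.47 ± 0.40 and summed tRNA-Cys-GCA 3FR_2 by -3.81 ± 0.26.

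In stimulated cultures 2359 features passed edgeR's test, 1221 higher and 1138 lower in EVs (1817 of 2506 higher with library totals). The list calls that held with an estimated correlation were the mitochondrial tRNAs (adjusted p = 6.61e-22 in camera, 0.000278 with an estimated correlation) and the snoRNAs (adjusted p = 9.41e-67 and 0.0111). The calls of 5FR_1 (adjusted p = 2.25e-28), miRNAs (3.92e-05), rRNA (0.00024) and activation-induced miRNAs (0.00616) were lost: adjusted p = 0.424, 0.795, 0.832 and 0.63 with an estimated correlation. Relative to TMM, library totals moved the median fold of all features by 0.14 in resting and 0.44 in stimulated EVs against cells, by 0.82 in stimulated against resting cells and 1.12 in EVs. The shift was 0.3 and 0.17 in the differences of ratio for stimulation and for GW4869, 0.31 and 0.14 in EVs and cells for GW4869 against DMSO, and -0.15 in DMSO against stimulated cells. RLE factors moved it by -0.12 in stimulated EVs against cells, -0.15 in stimulated against resting EVs and 0.14 in DMSO against stimulated cells.

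Whether the EV to cell ratio differed between stimulated and resting cultures was tested directly as a difference of the ratios. The ratio of all 10 mitochondrial tRNAs fell on stimulation, with a median of -4.66, and mt-Ti fell by -6.48 ± 0.36 (adjusted p = 1.52e-12). The ratio of Camk2b fell by -6.29 ± 0.31 (adjusted p = 1.72e-13), since its fragments stood at 80.28 ± 4.6 CPM in stimulated EVs and 84.46 ± 3.32 CPM in stimulated cells. The activation-induced miRNAs had 9 of 12 ratios lower (10 adjusted over the list alone) and 0 higher, with a median of -1.39, among them Mir132 at -1.76 ± 0.29 and Mir155 at -0.80 ± 0.24. The median of all miRNA ratios was -0.55, so Mir155 lay near its class, and library totals moved the median of all ratios up by 0.3. The 5FR_2 fragments had 80 of 109 ratios higher and 1 lower (86 and 1 adjusted over the list alone), with a median of 1.42, and the 3FR_2 fragments had 48 of 58 lower and 0 higher (51 and 0 adjusted over the list alone), with a median of -1.81. Among the named features, fragments in Fam49a (6.26 ± 0.70) and Mcf2l (5.28 ± 0.34) had the ratios that rose most. Tcf7 rose by 4.57 ± 0.55, and Obox1, Fam19a1, Obox3, Ispd and Tmem163 rose by 4.25 to 4.93. DMSO cultures were stimulated too, yet Tcf7, Obox1, Obox3 and Mcf2l stood in their EVs at 4.845, 4.152, 4.761 and 26.72 CPM, below the 20.29, 5.099, 5.124 and 32.83 CPM of resting EVs. For these 4 the DMSO EVs did not show the rise. Obox1 (chromosome 7, 15388948 to 15556866, plus strand) and Obox3 (15479825 to 15639902, minus strand) overlap. Their counts may therefore hold the same reads and are not separate evidence. No contrast of DMSO with resting EVs was run, and the vehicle cannot be told apart from the separate tabulation of the DMSO libraries. Fam49a (306.8 against 11.95 CPM) and Fam19a1 (338.4 against 17.37 CPM) were higher in DMSO than in resting EVs as well. In all, 1580 ratios passed edgeR's test, 668 higher and 912 lower, whereas with library totals 899 of 1576 were higher. Camera called the mitochondrial tRNAs (adjusted p = 1.67e-35, and 1.9e-05 with an estimated correlation), the activation-induced miRNAs (0.000578), 5FR_2 (1.01e-20) and 3FR_2 (4.13e-15). The last 3 were lost, with adjusted p = 0.644, 0.251 and 0.251 with an estimated correlation.

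Comparing stimulated with resting cells asked how the cells themselves differed between these cultures, with stimulation, culture time and earlier treatment not told apart. The miRNAs of naive and resting T cells had 9 of 10 features lower and 0 higher, with a median of -2.01. Mir150 (chromosome 7, 45121757 to 45121821, plus strand), a lymphocyte miRNA that targets Myb, fell by -3.95 ± 0.24, from 24120 ± 2490 to 1562 ± 302 CPM (adjusted p = 5.81e-13, n = 3), and Mir139 (chromosome 7, 101475376 to 101475443, plus strand) fell by -5.14 ± 0.38, as did its host gene Pde2a, whose 4 lines hold 2 different sets of counts in these libraries (-4.13 and -4.04). Mir26a-1 and Mir26a-2, 2 precursors of 1 miRNA, fell by -2.82 ± 0.21 and -2.83 ± 0.21. Such precursors are counted separately in the lists, so a list's numbers can hold 1 miRNA more than once. The let-7 family had 12 of 12 precursors lower (median -1.47), the miR-181 family and the miR-232724 clusters 6 of 6 each (-1.44 and -1.19), the miR-29 family 4 of 4 (-1.25), and the miR-30 and miR-15/16 families 5 of 6 each (-1.80 and -1.58), with Mir497 of the latter higher. With library totals the medians were -0.67 for let-7 (9 lower), -0.63 for miR-181 (5), -0.39 for miR-232724 (2), -0.44 for miR-29 (1), -0.99 for miR-30 (5) and -0.77 for miR-15/16 (5). There Mir98, Mirlet7e, Mir27a and Mir30a turned positive (0.14, 0.07, 0.08 and 0.39). The miR-17~92 and paralogous clusters had 6 of 15 lower, with a median of -0.30 that became 0.50 with library totals, where 8 were higher and 3 lower.

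Of the 12 activation-induced miRNAs 5 were higher and 7 lower in stimulated cells. Mir155 rose by 1.66 ± 0.18, from 3747 ± 308 to 11830 ± 770 CPM (adjusted p = 2.05e-08), and Mir146 rose by 1.76 ± 0.21, Mir132 by 1.10 ± 0.21, its neighbour Mir212 by 1.38 and Mir31 by 0.71 ± 0.23. Mir210 fell by -2.42 ± 0.24, Mir182 by -2.25 ± 0.25, Mir221 by -2.24 ± 0.20 and Mir21a (chromosome 11, 86584067 to 86584158, minus strand, in Vmp1) by -1.42 ± 0.30. All 70 rRNA features rose (median 2.31), as did 9 of 10 mitochondrial tRNAs (1.25), 87 of 152 snoRNAs against 10 that fell (0.76; 90 and 10 adjusted over the list alone) and 38 of 57 snRNAs against 4 that fell (1.73; 39 and 6 adjusted over the list alone). Many of the 70 rRNA features are n-R5s copies whose reads may be shared, so they are not 70 separate RNAs. Nuclear tRNA features had 41 higher and 511 lower of 780 (43 and 526 adjusted over the list alone), with a median of -1.05 that was -0.24 with library totals. The miRNAs had 23 higher and 125 lower (24 and 126 adjusted over the list alone), with a median of -0.64 that turned to 0.17 with library totals, where 62 were higher and 70 lower. The highest named features were fragments in Steap2 (5.31 ± 0.31), Kcns3, Evc, 4933404O12Rik, Ccdc85c, Slc5a11, Cabp7 and Inpp5f, all at 4.78 or more.

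In cells, 2033 features passed edgeR's test, 1014 higher and 1019 lower in stimulated cells, and with library totals 1991 of 2333 were higher. Camera called all groups just named except the activation-induced miRNAs, with adjusted p from 2.75e-24 for rRNA to 0.0367 for miR-17~92. With an estimated correlation none kept its call: adjusted p = 0.0734 for the naive and resting list, 0.185 for nuclear and for mitochondrial tRNAs, 0.243 for rRNA, miR-30, miR-232724 and miR-181, 0.271 for let-7 and miR-29, 0.338 for snRNAs, 0.347 for miRNAs and miR-15/16, 0.369 for snoRNAs and 0.55 for miR-17~92.

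How the vesicles differed between these cultures was read from stimulated against resting EVs, with the same limit. Mitochondrial tRNAs were lower in stimulated EVs in 10 of 10, with a median of -3.44, the opposite direction to the cells. The miRNAs had 8 higher and 201 lower (8 and 209 adjusted over the list alone), with a median of -1.21 that was -0.1 with library totals, where 37 were higher and 97 lower. Mir210 fell by -3.97 ± 0.25 (adjusted p = 2.26e-12), Mir182 by -3.75 ± 0.27, Mir150 by -3.05 ± 0.24 and Mir21a by -2.43 ± 0.31, while Mir155 rose by 0.86 ± 0.17 (adjusted p = 0.000158). The naive and resting list had 8 of 10 lower (9 adjusted over the list alone; median -2.14), the activation-induced list 10 of 12 lower and 2 higher, Mir155 and Mir146 (-2.38; 8 lower and 3 higher with library totals, -1.27), let-7 12 of 12 (-1.71), miR-29 4 of 4 (-2.07), miR-232724 6 of 6 (-1.96), miR-30 5 of 6 (-1.79), miR-181 4 of 6 (-1.35) and miR-15/16 5 of 6, with Mir497 higher (-1.71). The miR-17~92 and paralogous clusters had 15 of 15 lower (median -0.83), which turned to a median of 0.27 with library totals. With them the medians were -1.03 for the naive and resting list (7 lower and 2 higher), -0.60 for let-7 (11 lower), -0.95 for miR-29 (3), -0.85 for miR-232724 (6), -0.69 for miR-30 (5), -0.59 for miR-15/16 (4) and -0.23 for miR-181 (3 lower and 2 higher). There Mir132, Mir31 and Mir146b turned positive (0.45, 0.38 and 0.18).

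The 3FR_2 fragments fell in 58 of 58 features in stimulated EVs (median -1.95), and 61 of 70 rRNA features (0.89) and 47 of 57 snRNAs (1.09) rose, with 2 of each lower (62 and 2, and 47 and 4, adjusted over the list alone). The 2 lower rRNA features were those of mitochondria, mt-Rnr1 and mt-Rnr2, and the 2 snRNAs were Gm24136 and Rn7sk, chosen after their values were seen. Nuclear tRNA features had 76 higher and 246 lower (70 and 232 adjusted over the list alone), a median of -0.31, and turned with library totals to 460 higher and 68 lower, a median of 0.81. Named fragments in Fam49a (5.72 ± 0.44), Fgd5, Tbx3os1, Obox1, Obox3, Fam19a1, Tmem163 and Mcf2l were higher at 4.25 or more, and those in Zc3hav1 (chromosome 6, 38305286 to 38354603, minus strand), an antiviral zinc-finger gene, were lower by -5.25 ± 0.26, from 400.7 ± 21.5 to 10.53 ± 3.14 CPM. Fragments in Ctse, the gene of cathepsin E, fell by -5.24 ± 0.32, and those in 1700128A07Rik, Gm34015, Gm29554, Ppat, Gm20400 and 9030624G23Rik by -5.29 to -4.72. In EVs 2386 features passed edgeR's test, 1274 higher and 1112 lower, and with library totals 2880 of 3306 were higher. Camera called each of these lists, and only the mitochondrial tRNAs kept the call (adjusted p = 6.86e-15, and 0.00413 with an estimated correlation). For the others it gave adjusted p = 0.0704 for 3FR_2 and for the naive and resting list, 0.171 for miR-232724, 0.414 for miRNAs, miR-29 and the activation-induced list, 0.432 for let-7 and miR-30, 0.553 for snRNAs, miR-17~92, miR-15/16 and miR-181, and 0.764 for rRNA and nuclear tRNAs with an estimated correlation.

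Whether the sphingomyelinase inhibitor altered what the EVs carry was read from GW4869 against DMSO EVs. The snoRNAs had 78 of 152 lower and 0 higher (107 and 0 adjusted over the list alone), with a median of -0.79, and 33 were lower with library totals. The small nucleolar Rnu3a fell by -1.65 ± 0.27, from 112.6 ± 45.2 to 35.61 ± 8.7 CPM (adjusted p = 0.000429, n = 3). Mitochondrial tRNAs had 7 of 10 lower (9 adjusted over the list alone; median -1.20), and nuclear tRNA features 117 of 780 lower and 0 higher (106 and 0 adjusted over the list alone; median -0.47). The 5FR_1 fragments had 51 of 172 lower (68 adjusted over the list alone; median -0.59), led by 1 locus of tRNA-Gly-CCC 5FR_1 at -1.42 ± 0.21, from 686.6 ± 235 to 256.7 ± 30.8 CPM. The miRNAs had 48 of 254 lower and 0 higher (56 and 0 adjusted over the list alone), with a median of -0.53 that was -0.18 with library totals, where 3 were lower and 1 higher. Fragments in App (chromosome 16, 84949685 to 85173766, minus strand), the gene of the amyloid precursor protein, rose by 3.08 ± 0.37, from 25.45 ± 5.84 to 215.9 ± 113 CPM, and those in Ankrd11 by 2.45 ± 0.40.

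Among the miRNA lists in GW4869 EVs, 3 of 12 activation-induced miRNAs were lower (6 adjusted over the list alone), 4 of 10 of the naive and resting list (6), 2 of 12 let-7 (7), 7 of 15 miR-17~92 (10), 4 of 6 miR-15/16 (5) and 4 of 6 miR-181 (5), and 0 were higher in any of them. Other fragments that rose lay in Ano8, Plxna2, Cdc7, Tpm4, Ctnnd2 and Plppr1 (2.03 to 2.40), and those that fell in Lztr1, Sorcs2, Gm24601, Gm14634 and Fam163b (-1.88 to -1.29). Protein-coding genes as a class had 325 higher and 118 lower, with a median of 0.24. By edgeR's test 775 features passed, 348 higher and 427 lower, and with library totals 576 of 685 were higher. Camera called the snoRNAs (adjusted p = 1.47e-23), mitochondrial tRNAs (3.51e-07), nuclear tRNAs (1.3e-17), 5FR_1 (8.17e-17) and miRNAs (9.07e-14), and none held: adjusted p = 0.277, 0.087, 0.277, 0.277 and 0.349 with an estimated correlation. The 6 miRNA lists had adjusted p of 0.000136 to 0.00537 in camera, and adjusted p = 0.277 to 0.39 with an estimated correlation.

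These counts in EVs rested on single libraries. Without DMSO EVs replicate 2, 253 features passed, without GW4869 EVs replicate 3, 306, and without DMSO EVs replicate 1, 1138. The number of miRNAs lower was 3 without DMSO EVs replicate 2 and 3 without GW4869 EVs replicate 3, while that of snoRNAs was 26 to 91 over the 6 libraries left out in turn, and 36 without DMSO EVs replicate 2. Over the same 6 fits the protein-coding genes higher ran from 78 to 475, with 78 higher and 73 lower without DMSO EVs replicate 2, nuclear tRNA features lower from 20 to 204 and 5FR_1 lower from 17 to 76. When only the 6 libraries of these 2 groups were fitted, edgeR called 0 features, with 867 at an unadjusted p under 0.05 and a smallest adjusted p of 0.122, whereas the DESeq2 Wald test on all libraries called 829.

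**Figure D3:**
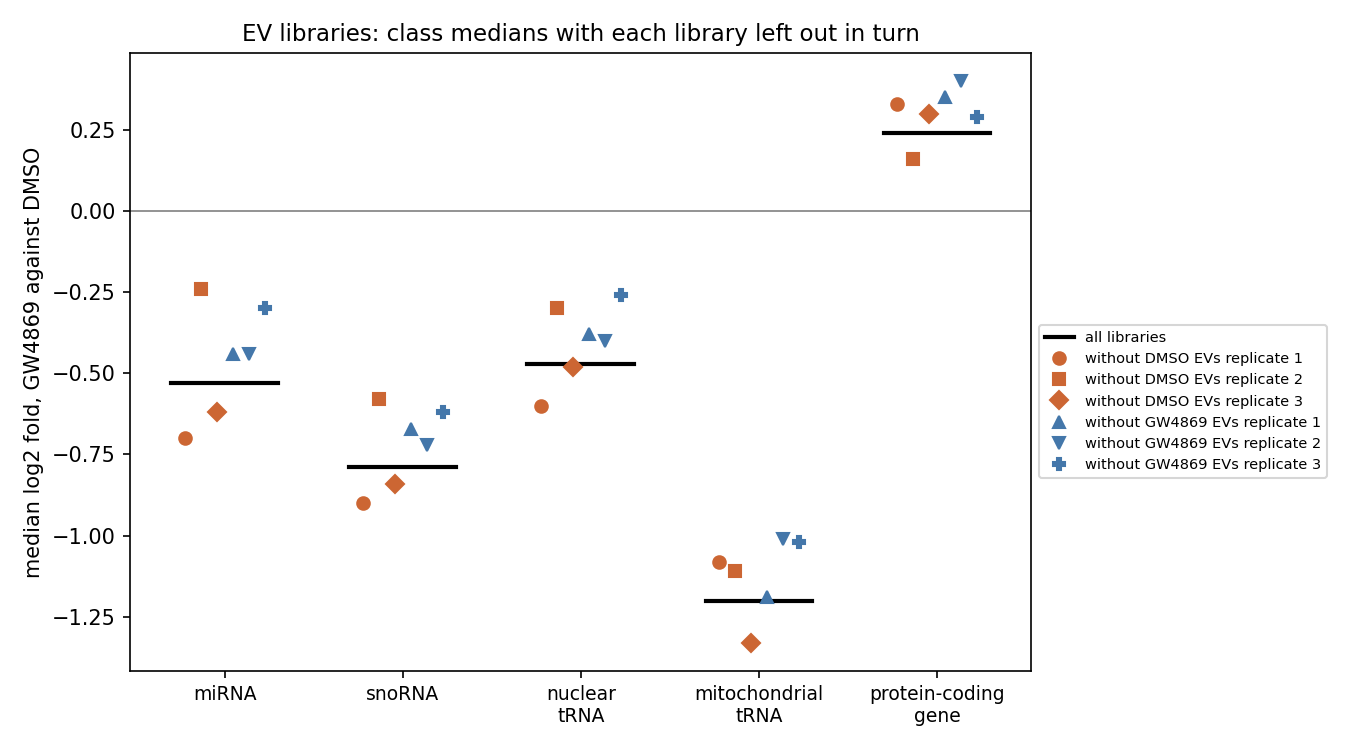
Median log2 fold of 5 classes (vertical axis) in GW4869 against DMSO EVs, with all libraries as lines and with each of the 6 libraries left out in turn as points, TMM scaling. The snoRNA median lies between -0.9 and -0.58 and the miRNA median between -0.7 and -0.24, and with library totals the medians are -0.45 and -0.18.

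In the cells, GW4869 against DMSO asked whether the inhibitor acted on the cells' own small RNAs. Fragments in Gnao1 (chromosome 8, 93809966 to 93969388, plus strand), the gene of a G protein alpha subunit, rose by 3.62 ± 0.30, from 12.13 ± 5.96 to 147.8 ± 22.4 CPM (adjusted p = 2.12e-08, n = 3). Those in Cd44, the gene of an adhesion receptor of activated T cells, rose by 1.16 ± 0.23, from 182.3 ± 9.38 to 408.6 ± 30.9 CPM (adjusted p = 0.00881), and those in Gm15662, Hacd1, Xylb, Slc22a14, Zfp185 and Gtf2i by 1.06 to 1.97. Mir147 (chromosome 2, 122640803 to 122640881, plus strand) fell by -1.03 ± 0.26 (adjusted p = 0.0335) with its host gene AA467197, and Mir221 fell by -0.75 ± 0.20 (adjusted p = 0.035, but 0.0667 with library totals and 0.0669 with only these groups fitted). Mir147 lost its call without any 1 of the 6 libraries (adjusted p = 0.0668 to 0.149), as did AA467197 (0.0554 to 0.132). Mir221 lost it without DMSO cells replicate 1 or 2 and GW4869 cells replicate 1 or 3 (0.127 to 0.176), and Cd44 without DMSO cells replicate 2 or 3 (0.0563 and 0.0516). Zfp185 lost it without DMSO cells replicate 2 or 3 and GW4869 cells replicate 1 (0.0592 to 0.085). Gtf2i lost it without each library but GW4869 cells replicate 1 (0.0596 to 0.139), while Gnao1, Gm15662, Hacd1, Xylb and Slc22a14 passed without each. Xylb (chromosome 9, 119357381 to 119393797, plus strand) and Slc22a14 (119169455 to 119365553, minus strand) overlap, so both may count the same reads. Of the miRNAs 1 was higher, Mir2137, and 3 were lower, Mir147, Mir221 and Mir466f-1 (1 and 0 adjusted over the list alone), and Mir2137 and Mir466f-1 are named as chosen after their values were seen. Mir2137 lies in an intron of Zfp185, so its reads may count for both: it went from 31.1 to 80.48 CPM and Zfp185 from 215.5 to 461.4 CPM. Of the snoRNAs and mitochondrial tRNAs none passed edgeR's test.

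In cells 132 features passed, 127 of them higher, 91 being protein-coding genes and 18 long non-coding genes. The count was 65 with RLE factors and 217 with library totals, and between 17 and 81 with 1 library left out: 46, 17 and 33 without DMSO cells replicate 1, 2 and 3, and 80, 81 and 42 without GW4869 cells replicate 1, 2 and 3. Camera called 19 of the lists, among them the miRNAs (median -0.22, adjusted p = 1.37e-09), and none with an estimated correlation (adjusted p = 0.916 for each).

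The difference of the EV to cell ratio between GW4869 and DMSO asked whether the inhibitor changed release relative to the cells. Ratios fell for 26 of 152 snoRNAs (40 adjusted over the list alone; median -0.65), for 59 nuclear tRNA features (median -0.48) and for 35 of 172 5FR_1 fragments (48 adjusted over the list alone; median -0.93), and rose for 0 in each of these classes. Of the miRNAs 5 of 254 had lower ratios (3 adjusted over the list alone; median -0.30): Mir125a, Mir2137, Mir5121, Mir6236 and Mir6240, chosen after their values were seen. Without DMSO EVs replicate 2 the snoRNAs had 15 lower ratios (median -0.45), the nuclear tRNAs 37 (-0.33), 5FR_1 27 (-0.67) and the miRNAs 3 (-0.02). The ratio of Gnao1 fell by -3.96 ± 0.40 (adjusted p = 1.27e-06) and that of Cd44 by -2.03 ± 0.33, with Lztr1, Gm15662, Zfp185 (the host gene of Mir2137), Gm24601, Sorcs2 and Arhgap21 between -2.63 and -1.94. Fragments in Gnao1, Cd44, Gm15662 and Zfp185 rose in GW4869 cells, so these ratios fell at least in part through the cells. The ratios of Dpp10 (3.05 ± 0.83, adjusted p = 0.0247), Coro2b, Ctnnd2, Gm29371, Tpm4, Cdc7, Ankrd11 and App rose by 2.25 or more. With only these 4 groups fitted, Ctnnd2 passed and the other 7 did not (adjusted p = 0.0553 to 0.0956). Without DMSO cells replicate 1 Dpp10 was at 1.39 (adjusted p = 0.276), and without GW4869 EVs replicate 3 Coro2b was at 1.72 (0.0616) and Cdc7 at 1.49 (0.104). Each of these 7 lost its call without at least 1 library, and among the lower ratios Gm24601 and Sorcs2 lost theirs with only these groups fitted (0.0718 and 0.113). With library totals Gm29371, Cdc7, Ankrd11 and Sorcs2 lost the call by edgeR (adjusted p = 0.0797, 0.0511, 0.0532 and 0.0533), and Sorcs2 also without GW4869 EVs replicate 3 (0.0502). By edgeR 334 ratios passed, 77 higher and 257 lower, and 104 of 304 were higher with RLE factors. The count was 162 with library totals and 45 with only these 4 groups fitted. It was 148 without GW4869 EVs replicate 3, 201 without GW4869 cells replicate 3, 213 and 221 without DMSO cells replicate 3 and 2, and 529 without DMSO EVs replicate 1. Camera called the snoRNAs (adjusted p = 1.34e-11), nuclear tRNAs (9.53e-10) and 5FR_1 (9.11e-15), each lost, with adjusted p = 0.5 with an estimated correlation.

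DMSO against stimulated cultures was meant to give the effect of the vehicle. The 12 DMSO and GW4869 libraries had also been tabulated apart from the 12 resting and stimulated ones, so vehicle and tabulation are confounded. The labels gave no antibody dose for the DMSO cultures, so an equal stimulation of both groups cannot be checked. Half-length fragments of the tRNA 5' end (5_half_up) were higher in DMSO cells in 96 of 102 features and lower in 0 (99 and 0 adjusted over the list alone), with a median of 1.51, and 1 locus of tRNA-Lys-CTT 5_half_up rose by 2.67 ± 0.23, from 55.04 ± 13.9 to 349.5 ± 20.5 CPM (adjusted p = 2.52e-08, n = 3). In DMSO EVs 62 of 102 were higher and 0 lower (74 and 0 adjusted over the list alone), with a median of 1.06. Mitochondrial tRNAs were higher in 9 of 10 in both cells (median 0.98) and EVs (1.21). The snRNAs Rnu5g (2.89 ± 0.32), Gm25313 and Gm22265, the snoRNA Gm22357 and Rmrp, the RNA of an RNase complex, rose in cells by 2.07 or more. In EVs, fragments in Tcf7 fell by -5.00 ± 0.40, from 165.6 ± 59 to 4.845 ± 3.77 CPM, and those in Obox1, Obox3, Mcf2l, Tbx3os1, Chd2, Prep and Foxo3 by -5.13 to -3.02.

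In cells 1279 features passed edgeR's test, 523 higher and 756 lower in DMSO, with 726 of 1357 higher with RLE factors and 376 of 1229 with library totals. In EVs 1038 passed, 601 higher and 437 lower, but 669 without stimulated EVs replicate 2 and 349 with only these groups fitted. The largest fold of DMSO against stimulated cells, 6.14 for a second line of Flt3l, is not a change of that gene: the line held 8 to 41 counts in resting and stimulated libraries, where the other Flt3l line held 176 to 2288. Camera called 5_half_up in cells (adjusted p = 2.06e-50) and EVs (9.41e-28), lost at adjusted p = 0.13 and 0.545 with an estimated correlation. It called the mitochondrial tRNAs in cells (1.56e-07, and 0.0483 with an estimated correlation) and in EVs (1.05e-05, lost at adjusted p = 0.174 with an estimated correlation). Over the 10 comparisons camera called 244 of 490 list tests and 7 with an estimated correlation: proline and threonine in resting EVs against cells, mitochondrial tRNAs and snoRNAs in stimulated EVs against cells, and mitochondrial tRNAs in stimulated against resting EVs, in the difference of ratio on stimulation and in DMSO against stimulated cells.

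Markers of other cell types were few. Mir451a, an erythroid miRNA, stood at 17.35 ± 12.2 CPM in resting cells and 74.9 ± 24.3 CPM in resting EVs, a rise of 2.11 ± 0.39 in EVs (adjusted p = 8.06e-05), and at 68.77 and 50.39 CPM in stimulated cells and EVs (-0.45 ± 0.34, adjusted p = 0.268). Mir126a, of platelets and endothelial cells, had 114.3 CPM in resting cells and 153 CPM in resting EVs. Of the liver list Mir192 was measured and fell by -2.24 ± 0.28 in stimulated against resting cells, and of the epithelial list Mir141 and Mir200c were measured. No myeloid, muscle or stromal marker was among the listed features, which were restricted to those with 4 or more counts in every library.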

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

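All tests of explanations reported here, and the counts over other splits of the libraries, were chosen only after the result was seen; the difference contrasts themselves were planned.

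The EV to cell ratio differed between stimulated and resting cultures for 1580 features and between GW4869 and DMSO cultures for 334, each by the test of the difference itself. For stimulation, 100 splits were counted, and 2 of them, the real one included, gave a result as large, a share under 0.05. The other was at 2660 and points to a structure of the samples: it keeps the cell libraries in place and exchanges the labels of all EV libraries, so that it adds the effect of stimulation on cells to that on EVs. The next highest split for stimulation called 1452. For GW4869, 1 of 100 splits, the real one, reached 334, with 158 as the highest of the others, so a share under 0.05 was met there too. Splits that mix the libraries of 2 conditions raise the spread within groups, whether or not the ratios differ. Neither share therefore tests the difference of the ratios, and no conclusion is drawn from them. For the 8 comparisons between 2 groups the 10 possible splits are too few for a share under 0.05. The real count in each was the 1 split that reached it, with the highest other at 0 for EVs against cells in resting (1513) and in stimulated cultures (2359), and at 1 and 2 for stimulated against resting cells (2033) and EVs (2386). It was 202 for GW4869 against DMSO EVs (775), 2 for GW4869 against DMSO cells (132), and 1 and 245 for DMSO against stimulated cells (1279) and EVs (1038).

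Mitochondrial tRNAs were lower in EVs than in cells in stimulated but not in resting cultures: the EV to cell ratio of the 10 mitochondrial tRNAs differed by a median of -4.66, those of mt-Ti, mt-Ta, mt-Ts2 and mt-Tm by -6.48, -5.49, -5.28 and -4.90, and that of the mitochondrial protein-coding gene mt-Nd5 by -4.74. Library totals in place of TMM factors moved the median of all ratios by 0.3. The mitochondrial median of -4.35 with library totals follows from that shift and is no separate test. A shift of that size is too small to be the source of the fall. RNA of whole cells in the resting EV preparations is argued against as the whole cause. It would raise nuclear snoRNAs as well, yet the mitochondrial tRNAs lay 2.19 above the snoRNAs in resting EVs (138.5% of the cell level against 30.4%), and all 10 of them lay above the 90th percentile of the snoRNAs, -0.58. Release of free cytoplasm or mitochondria by dying cells, the longer culture and the change of medium of the resting cells remain open and untested, and so does a change of sorting with activation.

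Under GW4869 the EV to cell ratio fell by a median of -0.65 for snoRNAs, -0.30 for miRNAs, -0.48 for nuclear tRNAs, -0.77 for mitochondrial tRNAs and -0.47 for snRNAs, but by -0.45, -0.02, -0.33, -0.64 and -0.23 without DMSO EVs replicate 2, and the snRNA share of EV counts was 1.02% under DMSO and 1.14% under GW4869. None of these 5 classes kept camera's call in that difference (adjusted p = 0.5 to 0.754 with an estimated correlation), and a fit of only the DMSO and GW4869 EVs called 0 features by edgeR, with 867 at unadjusted p below 0.05. In GW4869 against DMSO EVs themselves, in the model of all 8 groups, 36 snoRNAs were lower without DMSO EVs replicate 2. The number was 26 without GW4869 EVs replicate 3 and 33 with library totals. These counts rest on a spread shared by all 8 groups, which may be too small for these EVs. Within that model they argue against 1 DMSO EV library as the whole source of the lower snoRNAs. The snoRNA share was also 0.569 to 0.655% of counts in DMSO EVs and 0.387 to 0.447% in GW4869 EVs. TMM factors were not the whole source of the calls, but without an absolute amount of RNA another scaling stays open. These values do not cover the ratio, where 15 snoRNAs were lower without DMSO EVs replicate 2, so the part of that library stays open there. For the miRNAs in EVs, neither that library nor the scaling can be told apart from an effect of the inhibitor. There 3 were lower without DMSO EVs replicate 2, and 3 with library totals, and the libraries hold no measure of the absolute amount of RNA. If the difference holds in more libraries, a lower release under the inhibitor is a hypothesis for the snoRNAs, and it stays untested without vesicle counts.

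Half-length tRNA fragments were higher in DMSO than in stimulated libraries, in cells and in EVs. With the copies of a tRNA summed, 16 of 17 anticodons were higher in DMSO cells, so the rise was not confined to copies of a single anticodon. Summing leaves the fold of reads shared between copies unchanged, so it cannot test such reads as the source of the difference. Separate handling of the DMSO and GW4869 libraries cannot be told apart from the vehicle. The lowest share of 5_half_up counts in the 12 DMSO and GW4869 libraries, 0.467%, was 1.49 times the highest in the 12 resting and stimulated libraries, 0.313%, and no library with vehicle was tabulated with the latter. Library preparation and the vehicle could each be the source, and the design tests neither.

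Other features whose ratio differed with stimulation were Fam49a (6.26), Mcf2l (5.28), Obox1 (4.93), Fam19a1 (4.84), Obox3 (4.70), Tcf7 (4.57), Ispd (4.36) and Tmem163 (4.25), all higher, and Camk2b (-6.29), Gm26870 (-4.84) and Gm20628 (-4.75), lower. In the EVs of DMSO cultures, stimulated as well, Tcf7, Obox1, Obox3 and Mcf2l were not above their level in resting EVs (4.845 against 20.29, 4.152 against 5.099, 4.761 against 5.124 and 26.72 against 32.83 CPM), so their rise cannot be put down to stimulation alone. Obox1 and Obox3 overlap on opposite strands and may count the same reads. With GW4869 they were Dpp10 (3.05), Coro2b (2.72), Ctnnd2 (2.39), Gm29371 (2.36), Tpm4 (2.35), Cdc7 (2.34), Ankrd11 (2.34) and App (2.25), higher. Those lower with GW4869 were Gnao1 (-3.96), Lztr1 (-2.63), Gm15662 (-2.46), Zfp185 (-2.24), Cd44 (-2.03), Gm24601 (-2.02), Sorcs2 (-2) and Arhgap21 (-1.94). Of these, Gnao1, Gm15662, Zfp185 and Cd44 rose in GW4869 cells, which by itself lowers the ratio.

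Lists whose median ratio differed with stimulation were miRNAs (-0.55), nuclear tRNAs (0.73), snoRNAs (-0.90), rRNA (-1.46) and activation-induced miRNAs (-1.39). Among fragment kinds they were 3FR_1 (0.67), 3FR_1_down (-0.76), 3FR_2 (-1.81), 3_Internal (1.5), 3_Internal_half (1.73), 5FR_1 (0.96), 5FR_2 (1.42) and 5FR_S (1.31). By amino acid they were Asn (0.80), Asp (1.07), Gln (0.97), Glu (0.52), Gly (1.25), His (0.54), Lys (0.53), Pro (1.22), Val (0.82) and initiator Met (0.86). Of all these lists the mitochondrial tRNAs alone kept the call with an estimated correlation, and the others had adjusted p = 0.251 to 0.694 with an estimated correlation.

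With GW4869 the fragment kinds whose median ratio differed were 3FR_1 (-0.36), 3FR_2 (-0.98), 3FR_S (-1.39), 3_Internal (-0.50), 5FR_1 (-0.93) and 5FR_2 (-0.36). The amino acids were Ala (-0.83), Arg (-0.60), Asp (-0.50), Glu (-0.60), Gly (-0.49), Ile (-0.73), Leu (-0.61), Ser (-0.96), Trp (-0.56), Val (-0.94) and initiator Met (-0.68). None of the lists kept its call, with adjusted p = 0.5 to 0.754 with an estimated correlation.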

How the results depend on the processing

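The alternatives with tRNA copies summed and host genes left out, and those by class without single EV libraries, were tests chosen after seeing the data. Counts stayed within 1.5 times the reported one under every alternative run for stimulated EVs against cells, stimulated against resting cells and EVs, the difference of ratio on stimulation, and DMSO against stimulated cells. The others moved as follows. With copies summed and host genes left out, resting EVs against cells gave 994 of 3575 features tested, against 1513 of 4408. With library totals, GW4869 against DMSO cells gave 217 and its difference of ratio 162, and with RLE factors the cells gave 65. With only the groups compared, GW4869 against DMSO EVs gave 0, its difference of ratio 45 and DMSO against stimulated EVs 349. These fits estimate the spread from fewer libraries, with 4 against 16 residual degrees of freedom for GW4869 against DMSO EVs. The common dispersion there was also larger, 0.0969 against 0.0556. The spread shared by all 8 groups may therefore be too small for these EVs, and the adjusted p-values from it too small as well. With 1 library left out, the ranges were 253 to 1138 for GW4869 against DMSO EVs, 17 to 81 for cells, 148 to 529 for the difference of ratio and 669 to 1272 for DMSO against stimulated EVs. The cause was not tested where no construction is named. Among shares, the tRNA-derived result of 0.103 points moved to a log2 ratio to miRNAs of 0.472, which has another denominator, and the snRNA difference ran from 0.178 to 0.255 with 1 replicate number left out. Of the shares, 33 to 35 sets passed under every alternative. Camera called 244 lists, and 7 with an estimated correlation, which allows for members that move together. No feature named for the size of its change changed sign. Members of the lists did with library totals, among them Mir132 and Mir181a-1 in stimulated against resting EVs (-0.65 to 0.45 and -0.30 to 0.81). Library totals also turned the medians of some classes and lists given in the report, among them nuclear tRNAs in stimulated against resting EVs and miR-17~92 in cells, and the balance of calls in the difference of ratio on stimulation (668 of 1580 higher against 899 of 1576). RLE factors turned that of DMSO against stimulated cells (523 of 1279 against 726 of 1357). Of 2348 values of features named for the size of their change under the alternatives, 2253 kept direction and side of the threshold and 95 lost the call. Of the values kept, 155 came from fits without a filter, which equal the main fit by construction. The features had also been picked for large folds with a call, so this total does not measure how stable other calls are. Of 1960 list values, 1592 kept theirs, 299 lost the call and 69 gained one.

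The labels do not say whether replicate numbers pair the libraries, and they were treated as unpaired: same-number correlations of deviations from group means ran from -0.37 to 0.33. Replicate number as a block changed no count by more than 1.5 times, with 770 for GW4869 against DMSO EVs and 118 for the cells. The fits without a filter gave nothing to compare, since the filter removed 0 features, and the alternatives set out for normalized units (another pseudocount, a filter on low values) were not run, since the values were counts. The deposited files limited the comparison to features with at least 4 counts in each library.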

Other observations

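The tests in this part on features of the mitochondrial genome were chosen only after their values were seen. In stimulated cultures the other mitochondrial RNAs moved with the tRNAs: all 19 mitochondrial features were lower in stimulated EVs than in stimulated cells, with a median of -4.09 and a range of -6.84 to -3.04. The large ribosomal RNA of mitochondria, mt-Rnr2 (chromosome M, 1094 to 2675, plus strand), had 2278 ± 122 CPM in stimulated cells and 93.52 ± 11.2 CPM in their EVs, a fall of -4.61 ± 0.18 (adjusted p = 3.52e-16, n = 3). In resting cultures it had 1231 ± 37.3 CPM in cells and 568.8 ± 23 CPM in EVs (-1.11 ± 0.16, adjusted p = 1.4e-06), and the small one, mt-Rnr1, 433.9 and 467.2 CPM. In cells, 17 of the 19 rose on stimulation (median 1.64), and in EVs all 19 fell (-2.96). Under GW4869, 11 of 19 were lower in EVs (median -0.96), and in cells none passed edgeR's test.

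The 14 other small RNAs, which were not tested as a list, were each higher in resting EVs than in cells, with a median of 2.04. In stimulated EVs the glycine tRNA features had 65 of 106 higher and 12 lower (65 and 15 adjusted over the list alone; median 1.15) and the tyrosine features 12 of 12 higher (median 1.20), whereas threonine had 11 of 12 lower (12 adjusted over the list alone; median -1.63). Camera called these 3 lists (adjusted p = 1.19e-10, 0.00732 and 0.000382), and all were lost: adjusted p = 0.628, 0.546 and 0.144 with an estimated correlation.

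The counts in libraries of 1 group differed by more than counting error, with a chi-square per degree of freedom of 3.54 to 63.5 over the 24 pairs of libraries within groups, and no 2 libraries were identical. It was 33.0 to 63.5 among DMSO EVs and 8.19 to 32.5 among GW4869 EVs. Among stimulated EVs it was 5.25 to 11.9, and among resting EVs 9.66 to 36.7. Among cells it was 14.1 to 43.5 with GW4869 and 3.54 to 17.0 in the other groups. TMM factors ran from 0.56 to 1.76.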
